A study of Mus musculus with 3 samples.

How the data were processed

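RNA came from 3 replicate cultures of MGE cells taken from CD-1 mouse embryos at embryonic day 13. Cells were grown at 59000 cells per square centimetre with FGF2 at 40 ng/ml. From day 5 the cultures received AraC at 1 µM for 24 h to remove dividing cells, the medium was then changed 3 times 2 h apart, and the cells were kept for 2 more days. Labelled cDNA was made from 100 ng of total RNA with biotin and hybridized to a 1-colour Affymetrix array, 1 array per culture.

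The values used are those the authors deposited, 1 log2 signal per probe set and culture. Per the submitters' processing notes, they were made with oligo and RMA, which corrects background, normalizes the arrays to a common distribution and summarizes the probes of each set. The versions, the settings and any filter are not given in the sources used here. Values ran from 2.07 to 13.9, and the median of cultures 1, 2 and 3 was 6.57, 6.52 and 6.56. Arrays give no read depth, and the number of arrays limits the precision. Log2 levels were not compared between genes, since probe sets differ in how strongly they bind. No genome build is named in the files, so no coordinates are given.

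The table holds 41345 probe sets. Names came from the platform's probe table. In it 23521 probe sets carry 1 gene symbol (22180 genes), 1814 carry several and 16010 carry none, and only those with 1 symbol were used for gene results. Of the 23521, 23328 had their gene identifier in the RefSeq table of GRCm38.p6, and 0 of their symbols differed from it. Where a gene had more than 1 probe set (1073 genes, of which 464 had probe sets that disagreed), it was above background if any of its probe sets was, and the value printed is that of the probe set with the highest mean.

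The design, the gene lists, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise. Background was taken from 1440 probe sets of olfactory, vomeronasal and bitter taste receptor genes (median 4.37 log2 units), and the threshold was the 95th percentile of their means, 6.26. For the other 22081 probe sets (20751 genes) limma tested whether the mean of the 3 cultures exceeded the threshold, with a 1-sided moderated test of an intercept, and p was adjusted by Benjamini-Hochberg over all probe sets tested. Genes with an adjusted p under 0.05 are called above background. The moderation had 2.13 prior degrees of freedom.

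Gene lists numbered 25, with 483 genes, of which 449 were measured and 34 had no probe set of their own. For each list the number above background was compared with that of all other genes tested by Fisher's exact test, 2-sided, adjusted by Benjamini-Hochberg over the lists. Genes of a list are not independent, so these p values describe these 3 cultures. The pooled GABA and MGE lineage lists were compared in the same way with each of 11 lists of other cell types, without members that both held. The comparison of each list with the pooled negative control lists was added after the data were seen, because the negative control lists held genes above background. The pooled test of all ligand genes was added after the data were seen too.

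For each list with at least 3 genes above background (not the erythroid and interferon lists) and each culture, the deviation of each member above background from its own 3-culture mean was taken, and the median was placed among 10000 random lists of equal size, each gene drawn from the 200 genes nearest in level. Genes named in the text were the lead members of each list, all members above background where a list of another cell type or a negative control list had 5 or fewer, and the 10 genes above background with the largest SD, 103 genes in all, of which 82 were above background. Other genes are named to complete a count, because leaving out 1 culture changed their call, or as members of receptor and channel families, and were chosen after their values were seen. A lead member of a list is not reported here. Adjusted p values beside a left-out culture come from the same test on the other 2 cultures, with the threshold taken from those cultures.

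The call was tested on simulated data. Of 50 probe sets raised to 0.25, 0.5, 1 and 2 log2 units above the threshold, 31, 41, 47 and 50 were called in a fit of 22081 probe sets, and of 7179 with a true mean below the threshold 21 (0.293%) were. For the deviation per culture, of 20 simulated lists of 20 genes each, shifted by 0, 0.1, 0.2 and 0.4 log2 units in 1 culture, 0, 10, 20 and 20 lay above the 97.5th percentile. The simulated lists held genes drawn at random, so they do not show how often lists of genes that vary together reach such percentiles.

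The 13 alternatives to the call were the 99th and the 90th percentile as threshold, a threshold from other gene families not expected in brain (149 probe sets, 95th percentile 7.02), every culture above the threshold with no test, a margin of 1 log2 unit, an intensity trend in limma's prior, quantile normalization of the 3 arrays again, median centring, the mean of a gene's probe sets, leaving out dim probe sets, and leaving out each culture in turn. Agreement was also taken over probe sets above the threshold alone, and deviations over all measured members. Probe sets with several genes or none were left out of the gene results. No batch is given for the arrays in the sources used here, so none could be examined.

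Calls were made with R 4.3.3 and limma 3.58.1, and the rest with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.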

Results

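The cultures in this series were labelled as purified interneurons from the medial ganglionic eminence (MGE). The MGE is the part of the embryonic ventral forebrain that gives rise to many GABA-releasing interneurons of the cortex and striatum. The study's question, as far as it is known, was which secreted signals these interneurons make. Gene expression was measured by 1-colour array in 3 biological replicate cultures of embryonic day 13 CD-1 mouse tissue, and the 3 cultures form 1 group. No untreated, unpurified or other comparison group belongs to the series, so no gene is reported as higher or lower than in another condition. What can be asked is which genes gave signal above background, which gene groups they belong to, and how far the 3 cultures differed. Each array measured a whole culture, so which of its cells gave a signal, also for ligands, cannot be told. Values are on the log2 scale and are given as a mean ± SD over n = 3 cultures. The number of arrays limits their precision.

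Across all 41345 probe sets the 3 cultures gave closely similar values. The median SD of a probe set over the 3 cultures was 0.15 log2 units. Pearson's r across probe sets was 0.983 between cultures 1 and 2, 0.991 between cultures 1 and 3 and 0.986 between cultures 2 and 3, and Spearman's rho was 0.981, 0.99 and 0.984 for the same pairs. These correlations are across genes, which are not independent replicates, and carry no test. A total of 1596 probe sets (3.86%) spanned more than 1 log2 unit between their lowest and highest culture. With culture 2 left out the median SD was 0.10, against 0.13 without culture 1 and 0.15 without culture 3. An SD over 2 cultures tends to be lower than an SD over 3, so these values are compared only with each other.

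Of 20751 genes tested, 13155 (63.4%) gave signal above background in the cultures. Background was the 95th percentile, 6.26 log2 units, of the probe sets for olfactory, vomeronasal and bitter taste receptors, which serve sensory cells outside the brain regions studied. That line is lenient. Of 43 measured genes in the negative control lists (HOX genes of the hindbrain and spinal cord, and genes of muscle, liver, pancreas, testis and skin), 10 (23.3%) were above background. When a gene had to lie 1 log2 unit above the line, 1 of the 43 (2.33%) was above it, so both counts are given for each list below, the stricter as the count with a margin of 1. Since 63.4% of all genes were above background, a list with no more than that share can also exceed the negative control lists. A higher share than in those lists thus shows signal beyond such controls and not enrichment over other genes. Adjusted over the list alone, the counts were the same as over all genes tested except for the HOX genes (1), the oligodendrocyte lineage (18), the erythroid list (1) and the immediate early genes (15). The plot of list members shows all 25 lists against both lines.

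**Figure D1:**
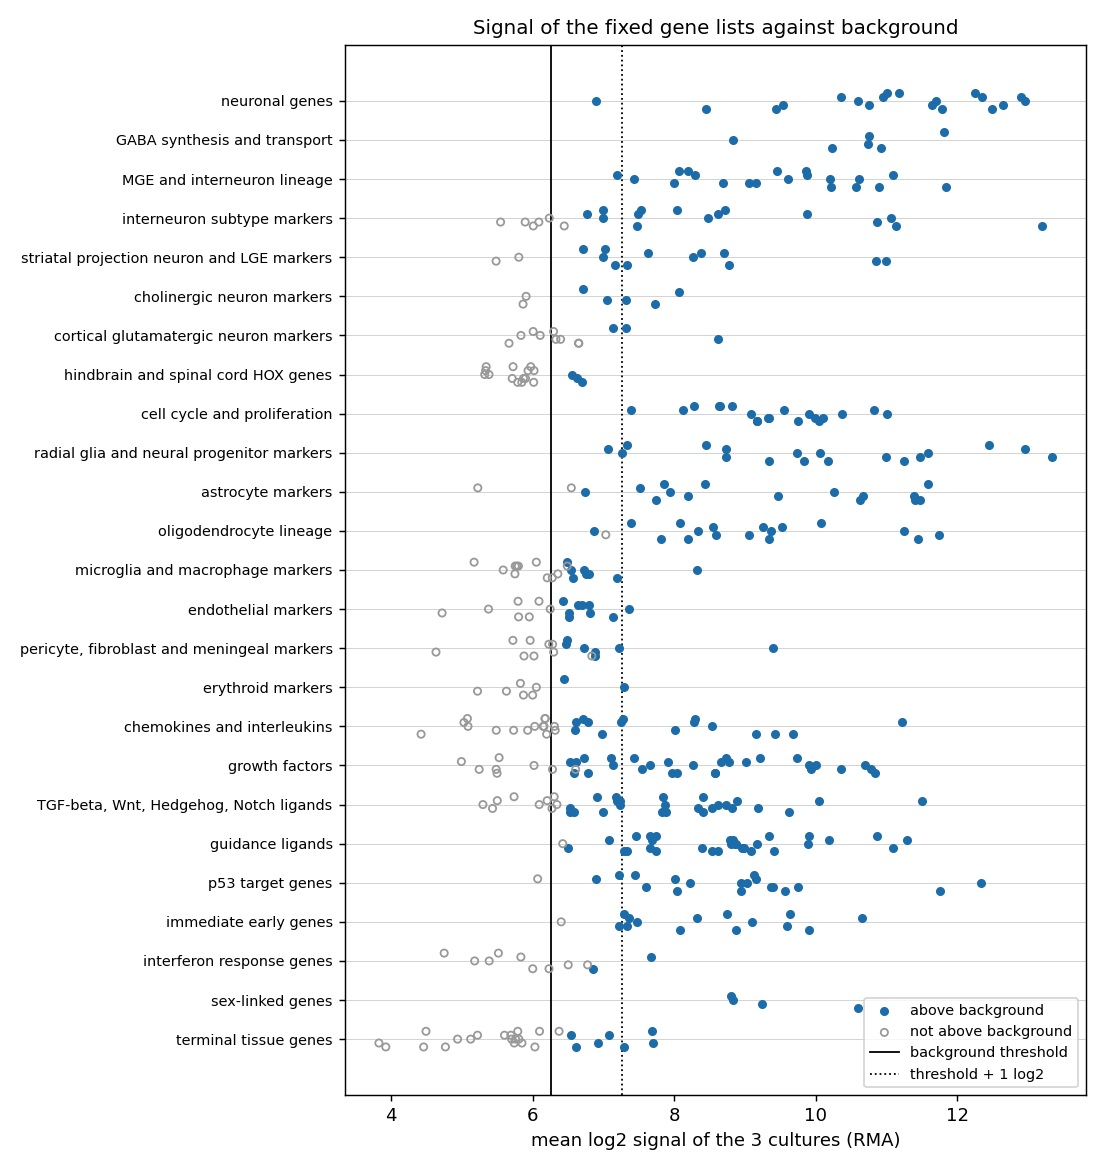
Mean log2 signal over 3 cultures of each measured member of the 25 gene lists, with filled points for genes above background, a solid line at the background threshold of 6.26 and a dotted line 1 log2 unit above it. All measured members of the neuronal, GABA, MGE lineage, cell cycle and progenitor lists were above background, against 10 of 43 members of the negative control lists.

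The cultures expressed the genes of GABAergic neurons of MGE origin. Gad1 (10.23 ± 0.53) and Gad2 (10.74 ± 0.26), the enzymes that make GABA, and Slc32a1 (8.83 ± 0.39), the transporter that loads GABA into vesicles, were all above background. So were Lhx6 (10.21 ± 0.10) and Nkx2-1 (9.16 ± 0.16), transcription factors that specify MGE interneurons, and Dlx2 (10.20 ± 0.10), a transcription factor of ventral forebrain GABAergic cells. Among general neuronal genes, Tubb3 (11.79 ± 0.16) and Dcx (11.64 ± 0.02), components of the neuronal cytoskeleton, Stmn2 (12.95 ± 0.09), a regulator of microtubules, and Snap25 (12.90 ± 0.20), a protein of synaptic vesicle release, were above background. As groups, 19 of 19 measured neuronal genes were above background (18 with a margin of 1), as were 6 of 6 genes of GABA synthesis and transport (6) and 20 of 20 MGE and interneuron lineage genes (18). By Fisher's exact test against all other genes, two-sided and adjusted over 25 lists, p was 0.00101 for the neuronal list, 0.00101 for the MGE lineage list and 0.136 for the short GABA list, where it was 0.0251 at the 99th percentile, 0.0494 with the other background families and 0.0208 with a margin of 1. Against the negative control lists, a comparison added after the data were seen, the adjusted p values were 2.69e-08, 1.71e-08 and 0.000941. Dlx1 had no probe set assigned to it alone and was not measured.

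Markers of interneuron subtypes were above background in part. Sst (13.20 ± 0.20), the neuropeptide somatostatin of an MGE-derived class, Npy (10.87 ± 0.12), neuropeptide Y, and Calb1 (9.88 ± 0.18), the calcium buffer calbindin, all passed the test. Chodl (6.09 ± 0.26) and Cort (6.45 ± 0.33), also markers of somatostatin cells, did not. Pvalb (6.24 ± 0.10, adjusted p = 0.946), the calcium buffer that marks the fast-spiking class in the mature brain, was not. Among markers of interneurons from the caudal eminence, Vip (5.55 ± 0.33), Lamp5 (5.90 ± 0.04) and Sp8 (6.01 ± 0.17) were not above background, while Htr3a (7.48 ± 0.23), Calb2 (8.04 ± 0.32) and Nr2f2 (7.54 ± 0.12) were. All other members of the list were above background, Reln, Cck, Id2 and Prox1 among them. The caudal markers, these other members, Chodl and Cort were named after their values were seen. The list had 15 of 21 members above background (10 with a margin of 1), which was not different from all other genes (Fisher's exact test, adjusted p = 0.549) but was more than in the negative control lists (adjusted p = 0.000590). Without culture 1, Cort passed the test (adjusted p = 0.00821), and without culture 2, Crhbp, which binds corticotropin-releasing hormone, did not (0.0646).

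Genes of dividing cells and progenitors were above background 2 days after AraC was washed out. AraC, a nucleoside analogue that kills cells during DNA synthesis, had been applied for 24 h from day 5. Mki67 (10.04 ± 0.19), a nuclear protein of cycling cells, Top2a (9.34 ± 0.15), a topoisomerase of replicating chromosomes, and Cdk1 (10.37 ± 0.16), the kinase that drives mitosis, were above background, and so were 20 of 20 measured cell cycle genes (19 with a margin of 1). Nes (9.35 ± 0.19) and Vim (12.95 ± 0.08), intermediate filament proteins of neural progenitors, and Sox2 (11 ± 0.32) and Pax6 (7.26 ± 0.20), transcription factors of progenitors, were among the 18 of 18 progenitor genes above background (15 with a margin of 1). Fisher's exact test against all other genes gave an adjusted p of 0.00101 for the cell cycle list and 0.00121 for the progenitor list, and against the negative control lists 1.71e-08 and 4.6e-08. Ccnb1 was not measured.

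Glial genes were above background too. The oligodendrocyte lineage had 17 of 18 genes above background (14 with a margin of 1), among them Pdgfra (11.45 ± 0.06), the growth factor receptor of oligodendrocyte precursors, and the lineage transcription factors Olig1 (11.74 ± 0.09), Olig2 (11.24 ± 0.13) and Sox10 (8.55 ± 0.36). Enpp6 (7.03 ± 0.85), named after its value was seen, was the exception. The astrocyte list had 15 of 17 genes above background (13 with a margin of 1), among them Aqp4 (8.20 ± 0.61), the astrocytic water channel, and Aldh1l1 (10.26 ± 0.45), an enzyme of folate metabolism used as an astrocyte marker. Gfap (7.74 ± 0.98), the intermediate filament protein of astrocytes, passed with all 3 cultures (adjusted p = 0.0158) but not without culture 1 (0.0888) or without culture 3 (0.10). S100b (6.55 ± 0.33, adjusted p = 0.0879), a calcium-binding protein of glia, did not pass, though it did without culture 2 (0.0219) and after quantile normalization or median centring, and neither did Gjb6. Adjusted p by Fisher's exact test against all other genes was 0.0135 for the oligodendrocyte lineage and 0.0798 for astrocytes, the latter 0.0117 without culture 2 (16 of 17), 0.0231 after quantile normalization, 0.0232 after median centring, 0.0423 at the 99th percentile and 0.0373 with a margin of 1, and against the negative control lists 7.3e-07 and 1.2e-05. Without culture 2, Enpp6 passed (0.0146), and without culture 3, Mobp did not (0.0640). Slc1a3 is in both the astrocyte and progenitor lists, and Olig2 in both the oligodendrocyte and progenitor lists.

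**Figure D2:**
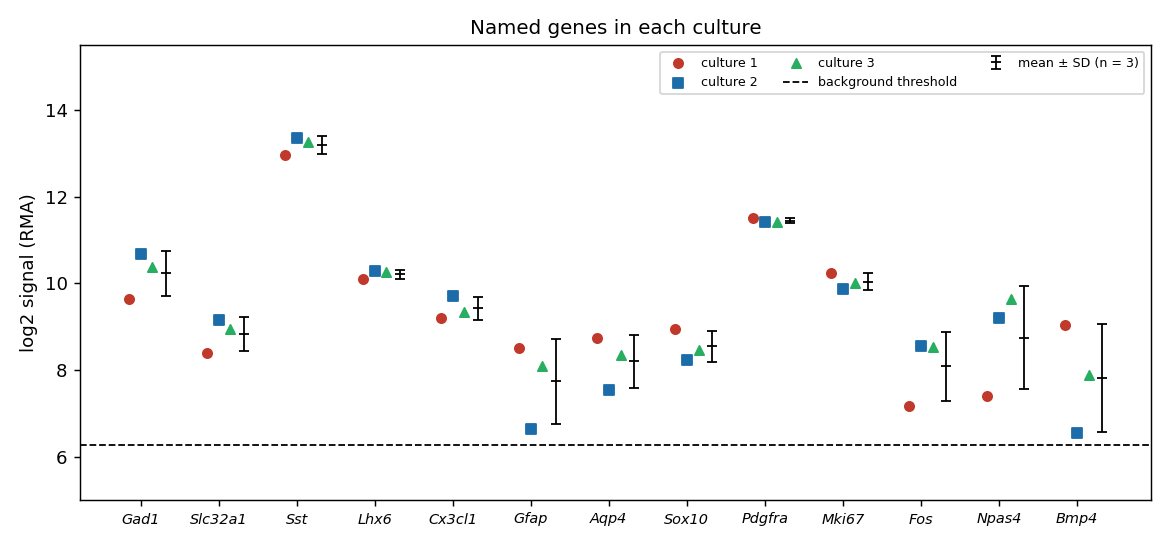
Log2 signal of 13 genes in each of the 3 cultures, with the mean ± SD (n = 3) and a dashed line at the background threshold of 6.26. Lhx6 and Pdgfra varied little between cultures (SD 0.10 and 0.06), and Sst and Mki67 somewhat more (0.20 and 0.19). Gad1 was 9.64, 10.67 and 10.37 in cultures 1, 2 and 3, Gfap was 8.51, 6.64 and 8.08, and Npas4 was 7.39, 9.21 and 9.64.

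Markers of other neurons were mixed, and those of cortical glutamatergic neurons were mostly at background in the mean of the 3 cultures. Slc17a7 (6.65 ± 0.55, adjusted p = 0.122) and Slc17a6 (6.40 ± 0.53), the vesicular glutamate transporters, and Neurod6 (5.84 ± 0.39) and Tbr1 (6.01 ± 0.22), transcription factors of cortical projection neurons, were not above background. The 3 of 12 that were (1 with a margin of 1) were Neurod2 (7.14 ± 0.16) and Neurog2 (7.32 ± 0.22), neurogenic transcription factors, and Lhx2 (8.62 ± 0.17), a forebrain transcription factor. Slc17a7, Slc17a6, Neurod6 and Tbr1 were each highest in culture 2, at 7.22, 7.01, 6.28 and 6.27, over the line of 6.26. In the same order they were 6.11, 6.11, 5.63 and 5.87 in culture 1 and 6.63, 6.07, 5.60 and 5.89 in culture 3. Their means thus do not show that they were at background in every culture. Chat (5.87 ± 0.21), the enzyme that makes acetylcholine, was not above background, while Slc18a3 (7.06 ± 0.42), the vesicular acetylcholine transporter, was, as were Lhx8 (8.07 ± 0.25), Isl1 (6.71 ± 0.16), Gbx2 (7.73 ± 0.03) and Ngfr (7.32 ± 0.41), which makes 5 of 7 cholinergic genes (2 with a margin of 1). Foxp1 (8.78 ± 0.13) and Bcl11b (10.85 ± 0.23), transcription factors of striatal projection neurons that interneurons also use, were among 12 of 14 striatal genes above background (7 with a margin of 1), and Ppp1r1b was not measured. Adjusted p by Fisher's exact test against all other genes was 0.0274 (a lower share) for the cortical list, 0.138 for the striatal list and 1 for the cholinergic list, and against the negative control lists 1, 0.0001 and 0.0283, the last of which was 0.187 at the 99th percentile and with the other background families, 0.0647 with a margin of 1 and 0.0979 at the 90th percentile. The cortical share was higher than that of the negative control lists at the 90th percentile (9 of 12, 0.0219). Without culture 1, Slc17a7 passed (adjusted p = 0.0410) and the cortical list (4 of 12) no longer differed from other genes (0.113), as without culture 3 (4 of 12, 0.121), when Emx2 passed (0.0446). The cortical list did not differ either after quantile normalization (0.0661), after median centring (0.0718), with every culture above the line and no test (0.0631) or at the 90th percentile (9 of 12, 1).

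Of the 17 HOX genes measured, 3 were above background, Hoxb5 (6.55 ± 0.03), Hoxd8 (6.70 ± 0.26) and Hoxd10 (6.62 ± 0.25), and none was with a margin of 1, whereas Hoxa3 (5.85 ± 0.02) and Hoxa4 (5.90 ± 0.10) were not. HOX genes pattern the hindbrain and spinal cord and serve as a negative control for forebrain tissue. Among genes of muscle, liver, pancreas, testis and skin, 7 of 26 were above background (1 with a margin of 1, the skin keratin Krt1, named after its value was seen). The myosins of skeletal muscle, Myh1 (4.46 ± 0.39), Myh2 (5.74 ± 0.29) and Myh4 (4.94 ± 0.32), were not. Both lists had a lower share than all other genes (Fisher's exact test, adjusted p = 0.00101 and 0.00118). Hoxb5 has 2 probe sets, of which 1 was called, and its call was lost with their mean (2 of 17 HOX genes). Without culture 1 the call of Hoxd10 was lost (adjusted p = 0.103) and 2 HOX genes were above background. Without culture 3 those of Hoxd8 (0.0752) and Hoxd10 (0.123) were lost and 1 HOX gene was, and without culture 2 that of Apoa2, a lipoprotein of liver, was lost (0.0761).

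Genes of blood and vessel cells lay close to background. In the microglial list 8 of 19 were above it, among them Cx3cr1 (7.20 ± 0.24), the receptor for the chemokine Cx3cl1, and Aif1 (6.54 ± 0.11), a microglial calcium-binding protein. Csf1r (6.36 ± 0.12), the receptor microglia need to survive, and Itgam (5.76 ± 0.15), an integrin of myeloid cells, were not, and with a margin of 1 the lysosomal gene Cd68 (8.33 ± 0.20) was alone. In the endothelial list 9 of 16 were above background and none was with a margin of 1. Pecam1 (6.52 ± 0.14) and Cdh5 (6.81 ± 0.27), adhesion proteins of vessel walls, and Kdr (7.36 ± 0.12), a VEGF receptor, were among them. In the pericyte, fibroblast and meningeal list 7 of 16 were above background, with Pdgfrb (6.88 ± 0.08), Rgs5 (6.88 ± 0.33) and Col1a1 (7.22 ± 0.22) among them, and only Acta2 (9.39 ± 0.88), smooth muscle actin, with a margin of 1. Cd68 and Acta2 were named after their values were seen. In the erythroid list 2 of 8 were above background, Epor (6.44 ± 0.13, adjusted p = 0.0497), the erythropoietin receptor, and Tspan33 (7.29 ± 0.18), and none was with a margin of 1. Hbb-y (5.87 ± 0.61), an embryonic globin, was not, and Hba-a1 was not measured.

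At the 95th percentile with all 3 cultures none of these 4 lists differed from all other genes by Fisher's exact test, the adjusted p being 0.0959 for microglia, 0.632 for endothelium, 0.159 for pericytes and 0.0959 for erythroid cells. At the 99th percentile and with a margin of 1 all 4 had a lower share than other genes. At the 99th percentile p was 0.000312, 0.00144, 0.00144 and 0.0150 in the same order, and with a margin of 1 it was 0.000418, 0.000195, 0.00196 and 0.0173. With the other background families it was 0.000165, 0.000545 and 0.000545 for microglia, endothelium and pericytes and 0.0502 for erythroid cells, whose share was lower with an intensity trend (0.0120) and without dim probe sets (0.0428). Against the negative control lists the endothelial share was higher (0.0345, but 1 at the 99th percentile, 1 with the other background families, 1 with a margin of 1 and 0.0824 at the 90th percentile), and the others were not (0.175, 0.224 and 1). At the 90th percentile, with 14 of the 43 control genes above the line, the microglial (13 of 19, 0.0180) and pericyte (11 of 16, 0.0219) shares were higher. Several calls near background were lost with only 2 cultures in the test, often with little change in the mean. For example, Aif1 had a mean of 6.54 both with all 3 cultures and without culture 3. Without culture 3 the microglial count was 3 of 19 (adjusted p = 0.000411 for a lower share than other genes), with Aif1 (0.0593), C1qb (0.0635), Fcer1g (0.0645), P2ry12 (0.0694) and Spi1 (0.0662) lost. The pericyte count was 5 of 16 without culture 2 (0.0384) and without culture 3 (0.0414), Rgs5 being lost in both (0.0592 and 0.0603) and with the mean of its 2 probe sets, Twist1 without culture 2 (0.0896) and Col3a1 without culture 3 (0.0683). The erythroid count was 1 of 8 without culture 1 (0.0128) and without culture 3 (0.0184), since Epor was lost (0.112 and 0.189). Pecam1 was lost without culture 1 (0.0714) and without culture 2 (0.216), Cldn5 without cultures 1 (0.0802) and 3 (0.116), Emcn without cultures 1 (0.0718) and 2 (0.0945), and Sox17 without cultures 2 (0.0911) and 3 (0.0784). Without culture 1, C1qb was lost (0.0528). Without culture 2, Aif1 was lost (0.0849) and Trem2 passed (0.0134).

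The GABA and MGE lineage genes, without the interneuron subtype list, were set against each list of another cell type. Of the pooled GABA and MGE lineage genes, 26 of 26 were above background. That share exceeded the shares in the cortical glutamatergic list by 75 percentage points (Fisher's exact test, two-sided, adjusted over 11 lists, p = 1.48e-05), the erythroid list by 75 points (7.06e-05), the microglial list by 57.9 points (4.1e-05), the pericyte list by 56.2 points (7.06e-05) and the endothelial list by 43.8 points (0.000933). It was not different from the cell cycle and progenitor lists, at 0 points each (adjusted p = 1), or from the oligodendrocyte lineage, at 5.56 points (0.5), astrocytes, at 11.8 points (0.207), and striatal neurons, at 14.3 points (0.183). Against cholinergic neurons, with Lhx8 left out as a member of both lists, the difference was 33.3 points (0.0591). The striatal difference was 46.2 points at the 99th percentile (0.00188) and the cholinergic one 79.3 points (0.000376). At the 90th percentile the cortical difference was 25 points (0.0574), and leaving out any 1 culture changed none of these 11 calls.

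Of 132 measured genes in the 4 ligand lists, 99 (75%) were above background, against 63.3% of other genes (Fisher's exact test, unadjusted p = 0.00491). With a margin of 1 it was 68 (51.5%) against 47.6% (exact p = 0.383). Leaving out Fgf11 to Fgf14, FGF homologous factors that stay inside the cell, made it 95 of 128 (74.2%, exact p = 0.00997), and 64 (50%, exact p = 0.596) with a margin of 1, and these pooled tests were added after the data were seen. Among chemokines, Cx3cl1 (9.42 ± 0.27, adjusted p = 1.29e-05), a neuronal ligand for the microglial receptor Cx3cr1, was at 9.20, 9.72 and 9.35 in the 3 cultures, and Cxcl14 (8.54 ± 0.22) was also above background. Ccl2 (6.62 ± 0.22, adjusted p = 0.0182), which attracts monocytes, passed with all 3 cultures but not without culture 1 (0.0711) or culture 2 (0.127). Cxcl12 (6.32 ± 0.09, adjusted p = 0.296), the chemokine that guides migrating interneurons, did not pass. Chemokines numbered 10 of 14 above background but 4 with a margin of 1, which were Cx3cl1, Cxcl14, Ccl25 and Ccl27a. Interleukins and other cytokines numbered 5 of 16 (4 with a margin of 1), which were Il18, Csf1, Lif, Ctf1 and Mif. Together they made 15 of 30 (8 with a margin of 1), a share not different from all other genes (Fisher's exact test, adjusted p = 0.166), but lower at the 99th percentile (0.0251), with the other background families (0.0167) and with a margin of 1 (0.0373). Against the negative control lists it was higher (0.0332, with 0.0605 at the 99th percentile and with the other background families, and 0.00394 with a margin of 1).

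Growth factors had 29 of 37 members above background (21 with a margin of 1). The vascular growth factors Vegfa (8.58 ± 0.36), Vegfb (10.79 ± 0.10) and Vegfc (7.65 ± 0.15) were among them, as was Pdgfa (8.77 ± 0.11), the ligand of the precursor receptor Pdgfra. The FGF family had 8 of 9 above background (5 with a margin of 1), of which Fgf11, Fgf12, Fgf13 and Fgf14 are not secreted, the EGF family and neuregulins 6 of 8 (5), the VEGF, PDGF and angiopoietin genes 7 of 9 (5), and the neurotrophin and GDNF families 1 of 3 (0), Nrtn, with Bdnf (6.02 ± 0.26) and Gdnf (5.00 ± 0.09) below the call. In the list of TGF-beta, Wnt, Hedgehog and Notch ligands 25 of 34 were above background (15 with a margin of 1). They included Tgfb1 (6.99 ± 0.24), Tgfb2 (8.82 ± 0.28) and Tgfb3 (7.87 ± 0.18) but not Bmp2 (6.21 ± 0.09), a bone morphogenetic protein. Notch ligands numbered 7 of 7 (5 with a margin of 1), Wnt ligands 6 of 9 (3) and the TGF-beta and BMP families 10 of 15 (6). Hedgehog ligands numbered 2 of 3 (1), which were Ihh and Dhh, with Shh (5.74 ± 0.12) below the call. Adjusted p by Fisher's exact test against all other genes was 0.0959 and 0.339 for these 2 lists, and against the negative control lists 3.95e-06 and 2.56e-05. Calls were lost for Angpt1 without cultures 1 (0.0886) and 2 (0.223) and with the mean of its probe sets, Nrtn without cultures 1 (0.0943) and 3 (0.117), Nrg4 without cultures 2 (0.395) and 3 (0.183), Bmp4 without cultures 1 (0.0988) and 3 (0.125), and Gdf10 without culture 2 (0.0547), and Bmp6 passed without culture 2 (0.0396).

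Guidance ligands, which steer axons and migrating cells, had 30 of 31 members above background (24 with a margin of 1), a higher share than all other genes (Fisher's exact test, adjusted p = 0.000447) and than the negative control lists (1.47e-09). The secreted semaphorins Sema3a (7.33 ± 0.29), Sema3c (8.40 ± 0.30) and Sema3e (7.08 ± 0.51) were above background and Sema3d (6.43 ± 0.21, adjusted p = 0.125) was not. All 8 ephrins (6 with a margin of 1) and all 8 measured netrin, slit, Rgm and draxin genes (7) were above background, with 14 of 15 semaphorins (11). Sema3e was lost without culture 2 (0.101) and culture 3 (0.0845), Efna1 without cultures 1 (0.0561) and 3 (0.0870), and Sema3d passed without culture 3 (0.0277).

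Target genes of p53, the transcription factor activated by DNA damage, were above background in 18 of 19 cases (15 with a margin of 1). Cdkn1a (11.75 ± 0.13), an inhibitor of cyclin-dependent kinases, Mdm2 (9.36 ± 0.06), which marks p53 for degradation, and Ccng1 (12.33 ± 0.12), a cyclin induced by p53, were among them, whereas Fas (6.07 ± 0.12), named after its value was seen, was not and Bax was not measured. Fisher's exact test against all other genes gave an adjusted p of 0.00887, and against the negative control lists 4.06e-07. Without cultures that had no AraC, whether these genes were raised by the drug is not answered here. Sex-linked genes of both kinds were above background, 4 of 4 measured (4 with a margin of 1). Xist (10.59 ± 0.37), the RNA that silences an X chromosome in females, and the Y-linked genes Eif2s3y (9.23 ± 0.17), Kdm5d (8.83 ± 0.01) and Uty (8.81 ± 0.22) were all above background, and Ddx3y was not measured. The adjusted p of this short list was 0.345 against all other genes and 0.00861 against the negative control lists.

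Immediate early genes, which neurons switch on within minutes of activity or stress, were above background in 14 of 15 cases (8 with a margin of 1). Fos (8.09 ± 0.80), Fosb (7.21 ± 0.91) and Fosl2 (9.10 ± 0.77), subunits of the AP-1 transcription factor, were above background and Ier2 (6.40 ± 0.12), named after its value was seen, was not. Interferon response genes were mostly at background, with 2 of 11 above it, Rsad2 (6.85 ± 0.08) and Ifitm3 (7.68 ± 0.21), of which Ifitm3 was so with a margin of 1, both named after their values were seen. Ifit1 (6.0 ± 0.11), Ifit3 (6.78 ± 0.57, adjusted p = 0.0705) and Isg15 (5.18 ± 0.06), antiviral proteins induced by interferon, were not. Against all other genes the immediate early share was higher (Fisher's exact test, adjusted p = 0.0304) and the interferon share lower (0.00887), and against the negative control lists p was 5.84e-06 and 1. Both calls changed with the setting and with only 2 cultures in the test. The immediate early share did not differ from other genes at the 99th percentile (9 of 15, 0.515), with a margin of 1 (0.867), with the other background families (0.0502) or without dim probe sets (0.0528), and the interferon share did not at the 90th percentile (6 of 11, 0.329). With a culture left out, the immediate early share did not differ without culture 2 (10 of 15, 0.823) or culture 3 (13 of 15, 0.108), and the interferon share did not without culture 2 (3 of 11, 0.0529) or culture 3 (3 of 11, 0.0569). Fosb was lost without culture 2 (0.199) and culture 3 (0.106). Without culture 2, Fos (mean 7.86, adjusted p = 0.0620), Npas4 (0.0780) and Egr3 (0.0512) were lost and Ifit3 passed (0.00413), and without culture 3, Usp18 passed (0.0156).

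The 3 cultures differed in gene groups that mark cell types. Culture 1 was higher in glial and progenitor genes and lower in neuronal genes than the other cultures, and culture 2 was the reverse. The median deviation from the 3-culture mean in cultures 1, 2 and 3 was 0.36, -0.46 and 0.04 log2 units for the 15 astrocyte genes above background, 0.39, -0.31 and -0.08 for the 17 oligodendrocyte lineage genes, and 0.21, -0.16 and -0.06 for the 18 progenitor genes. For the 19 neuronal genes it was -0.18, 0.12 and 0.03, and for the 6 GABA genes -0.28, 0.19 and 0.08. Cell cycle genes deviated by 0.13, -0.03 and -0.08. In culture 1 all 15 astrocyte genes and all 18 progenitor genes were above their own means, as were 16 of 17 oligodendrocyte lineage genes, against 2 of 19 neuronal genes.

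Immediate early genes followed another order, at -0.35, 0.01 and 0.36, with 1, 8 and 13 of 14 genes above their means in cultures 1, 2 and 3. Growth factors deviated by -0.14, 0.10 and 0.04, and p53 targets by -0.01, 0.14 and -0.11. Against 10000 random lists of equal size and like level, the astrocyte, oligodendrocyte lineage and progenitor lists lay at percentile 100 in culture 1 and 0 in culture 2, and the immediate early list at 0 in culture 1 and 100 in culture 3. Among lists whose deviations are not given above, the 5 cholinergic genes deviated by 0.24 and the 3 HOX genes by -0.24 in culture 2, the latter being -0.02 over all measured HOX genes. The MGE lineage list stayed within 0.09 of its mean in every culture, at percentile 2.61, 68.5 and 99.2. Each culture is a single sample, so these deviations are descriptive and carry no test here. Tests across genes on some of the differences, given at the end, describe these arrays alone. The directions given held after quantile normalization and after median centring, except that the small cell cycle deviation in culture 2 all but vanished after centring.

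**Figure D3:**
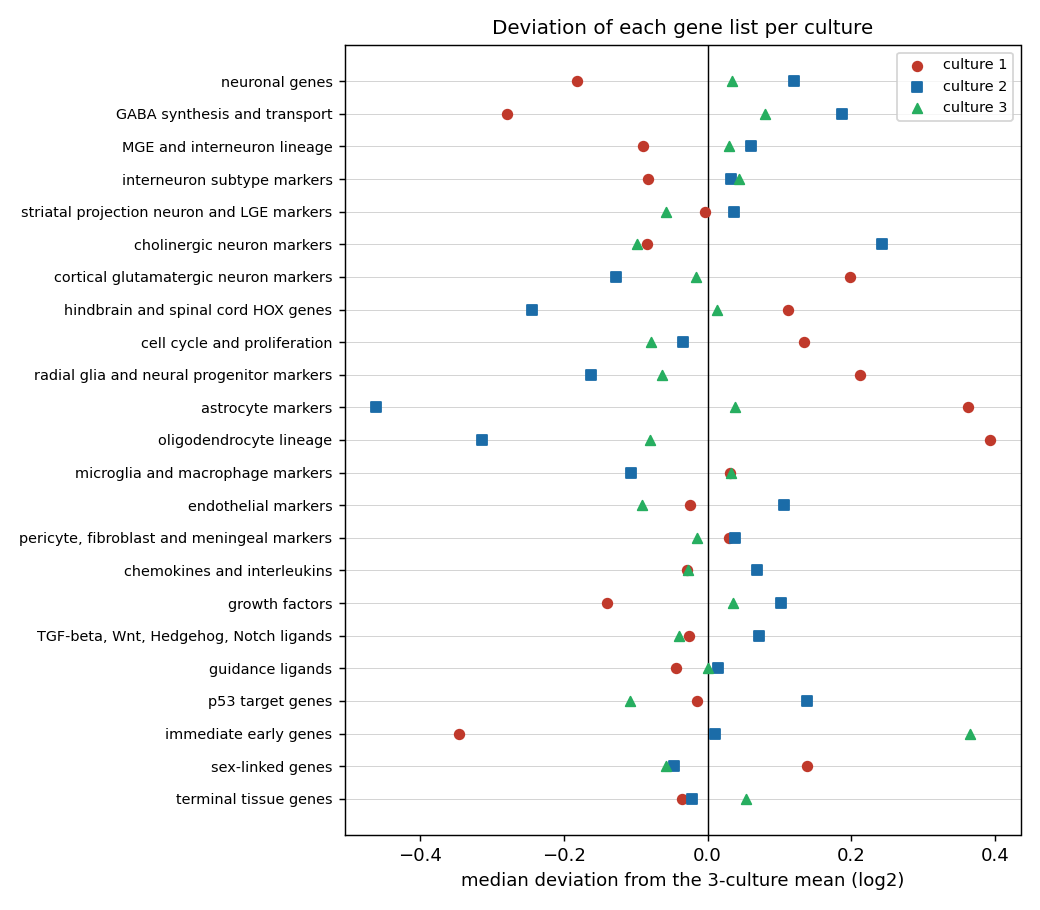
Median deviation of each gene list from its mean over 3 cultures, in log2 units, over members above background, for cultures 1, 2 and 3. Culture 1 was highest and culture 2 lowest in the astrocyte (0.36 and -0.46), oligodendrocyte lineage (0.39 and -0.31) and progenitor (0.21 and -0.16) lists.

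Among genes above background, 173 (1.32%) spanned more than 1 log2 unit between cultures. Culture 1 was the lowest in 109 of them, culture 2 in 49 and culture 3 in 15, and the highest was culture 1 in 57, culture 2 in 104 and culture 3 in 12. The 10 genes with the largest SD fell into contrasting groups. Those lowest in culture 1 were Npas4 (8.75 ± 1.19) and Nr4a3 (9.60 ± 1.08), transcription factors induced by neuronal activity, Kcnk9 (9.25 ± 1.02), a potassium channel, Crhbp (8.48 ± 1.01), which binds corticotropin-releasing hormone, Cfap206 (7.87 ± 1.15), a protein of cilia, Tecrl (8.48 ± 0.97) and Adamts15 (7.27 ± 0.94), a protease of the extracellular matrix. Those lowest in culture 2 were Bmp4 (7.83 ± 1.25), a bone morphogenetic protein, Pla2g7 (8.01 ± 1.04), a secreted phospholipase, and Gfap (7.74 ± 0.98). Bmp4 was 9.04, 6.55 and 7.89 in cultures 1, 2 and 3, and Npas4 was 7.39, 9.21 and 9.64. Several of these calls were lost with only 2 cultures in the test, most of them without either of 2 cultures, while the mean stayed above the threshold. For example, the mean of Bmp4 was 7.22 without culture 1 and 7.79 without culture 3. Bmp4 was lost without culture 1 (adjusted p = 0.0988) and culture 3 (0.125), Pla2g7 (0.0811 and 0.0766) and Gfap (0.0888 and 0.10) without the same cultures, Cfap206 without cultures 2 (0.148) and 3 (0.115), Adamts15 without cultures 2 (0.276) and 3 (0.187), and Npas4 (0.0780) and Crhbp (0.0646) without culture 2.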

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

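Both results here come from probe sets that the gene results do not use, and the same test and threshold were applied to each set on its own. Of the 16010 probe sets with no gene name, 5880 gave signal above background. Of the 1814 probe sets that carry several gene symbols, 978 did. Both shares were lower than the 63.4% of genes tested and higher than the 23.3% of negative control genes, which are counted per gene. No explanation was tested for either.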

How the results depend on the processing

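The comparison with the negative control lists was chosen after the data were seen, and all other alternatives before. The number of genes above background ranged from 9880 with a margin of 1 log2 unit to 15050 at the 90th percentile, and was 12635 to 12965 with 1 culture left out, within 1.5 times the reported 13155 under all 13 alternatives. Of the 103 named genes, 28 lost their call at the 99th percentile, 30 with a margin of 1 and 26 with the other background families, and 10 gained one at the 90th percentile. The changed counts at other thresholds follow from where the line was drawn, since signal over background is what limits these calls. For the other changes the cause was not tested. No paired analysis was possible because the series has 1 group.

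At the 99th percentile the counts of list members above background were 7 for striatal, 2 for cholinergic, 1 for cortical glutamatergic, 0 for HOX, 1 for microglial, 1 for endothelial, 1 for pericyte, 0 for erythroid, 8 for chemokine and interleukin, 15 for TGF-beta, Wnt, Hedgehog and Notch, 9 for immediate early, 1 for interferon and 3 for terminal tissue genes. With a margin of 1 log2 unit they were 7 for striatal, 2 for cholinergic, 1 for cortical glutamatergic, 0 for HOX, 1 for microglial, 0 for endothelial, 1 for pericyte, 0 for erythroid, 8 for chemokine and interleukin, 15 for TGF-beta, Wnt, Hedgehog and Notch, 8 for immediate early, 1 for interferon and 1 for terminal tissue genes. With the other background families they were 2 for cholinergic, 0 for HOX, 1 for microglial, 1 for endothelial, 1 for pericyte, 1 for erythroid, 8 for chemokine and interleukin, 16 for TGF-beta, Wnt, Hedgehog and Notch, 1 for interferon and 3 for terminal tissue genes. At the 90th percentile they were 9 for cortical glutamatergic, 13 for microglial, 11 for pericyte, 4 for erythroid, 23 for chemokine and interleukin and 6 for interferon genes, and with an intensity trend 1 for erythroid genes. With 1 culture left out the counts were 1 to 3 for HOX, 3 to 8 for microglial and 1 to 2 for erythroid genes.

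The lead of the pooled GABA and MGE lineage lists over the striatal list was 46.2 points at the 99th percentile (adjusted p = 0.00188), 42.9 with the other background families (0.00123) and 42.3 with a margin of 1 (0.00687), past the threshold it did not reach as reported. Over the cholinergic list it was 79.3 (0.000376), 83.3 (6.47e-05) and 75.3 (0.00127) under the same settings, and over the astrocyte list 23.5 with the other background families (0.0265). At the 90th percentile the lead over the cortical glutamatergic list was 25 and no longer passed (0.0574). The interneuron subtype list was not in the pool. At the 99th percentile it had 12 of 21 members above background, against 7 of 14 in the striatal list.

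The median SD between cultures was 0.0986 to 0.147 with 1 culture left out. Over probe sets above the threshold Pearson's r was 0.972 between cultures 1 and 2 and 0.986 between cultures 1 and 3. In culture 2 the deviation of guidance ligands was -0.0211 after quantile normalization and 0.0486 after median centring, and that of pericyte genes 0.0715 after centring. Over all measured members the deviation in culture 2 was 0.105 for striatal, -0.0171 for HOX and 0.00684 for chemokine and interleukin genes. That of pericyte genes in culture 3 was 0.0503, against -0.0145 over members above background. For the cortical glutamatergic list the sign reversed in cultures 1 and 2. Its deviation was 0.199 and -0.127 there over the 3 genes above background, but -0.184 and 0.118 over all measured members.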

Other observations

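The families and all the tests in this part were chosen after the results were seen. Receptors and channels of kinds through which neurons receive signals were above background in part, against 63.4% of all genes. No family was tested for enrichment, and which cells of the cultures expressed these genes cannot be told. Of 16 GABA-A receptor subunits 9 were above background (8 with a margin of 1 log2 unit), among them Gabra2 (10.89 ± 0.39, SD, n = 3), Gabra5 (10.40 ± 0.37) and Gabrg1 (10.89 ± 0.10), while Gabra6 (4.27 ± 0.11), a subunit of cerebellar granule cells, was not. Of 15 ionotropic glutamate receptor subunits 14 were (12), the exception being Grin2c (6.31 ± 0.32), which passed without culture 2 (adjusted p = 0.0444). The calls of Grin2a without cultures 1 (0.0743) and 3 (0.0691) and of Grin3b without cultures 2 (0.122) and 3 (0.0683) were lost. Of 5 glycine receptor subunits Glra2 (9.70 ± 0.16) and Glrb (10.02 ± 0.19) were above background, and Glra3 (7.25 ± 1.11) was not, though it passed without culture 1 (0.0117), at the 90th percentile and after quantile normalization or median centring. The counts were 5 of 7 for metabotropic glutamate receptors (3 with a margin of 1), 4 of 16 for nicotinic receptor subunits (3), 4 of 5 for muscarinic receptors (2), the exception Chrm5 (6.78 ± 1.10) passing without culture 1 (0.0491), and 9 of 14 for serotonin receptors (1, Htr2a at 9.89 ± 0.17), where Htr1a was lost without cultures 2 (0.0629) and 3 (0.101).

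Voltage-gated sodium and calcium channels were above background in part too. Of 8 sodium channel alpha subunits the 4 above background (4 with a margin of 1) were Scn1a (8.01 ± 0.41), Scn2a (9.95 ± 0.14), Scn3a (9.24 ± 0.20) and Scn8a (9.10 ± 0.16), the brain forms, while Scn9a, Scn10a and Scn11a, forms of sensory neurons, and Scn7a were not. Of 10 calcium channel alpha-1 subunits 8 were (8), the exceptions being Cacna1f and Cacna1s, the retinal and skeletal muscle forms. Two-pore potassium channels (Kcnk), a family apart from the voltage-gated ones, numbered 9 of 13 (5). Protocadherins, adhesion proteins of neurons, numbered 33 of 35 (26), of which Pcdh12 was lost without cultures 2 (0.306) and 3 (0.135) and Pcdhb5 without cultures 2 (0.110) and 3 (0.0933).

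A total of 1939 probe sets (4.69%) had the same value in at least 2 cultures to within 1e-06 log2 units, and 159 (0.385%) in all 3. The median SD was 0.157 over probe sets with no tie and 0.0686 over those with one.

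The series has 1 group, so no difference between groups was weighed against the patterns below, and the tests concern the arrays and the makeup of the cultures. Comparisons between cultures set 1 array against another, so their p values are across genes, which are not independent, and describe these arrays alone. Astrocyte, oligodendrocyte lineage and progenitor genes were high in culture 1 and low in culture 2. Differences in intensity distribution left in the deposited values do not account for this. The median difference of culture 1 minus culture 2 over 48 genes was 0.564 log2 units after quantile normalization, against 0.543 as deposited. RMA had already normalized these values, so a second pass could change little. Other differences between the arrays were not tested. A different share of oligodendrocyte lineage cells with an unchanged makeup of stages stays open: 5 precursor genes (Pdgfra, Cspg4, Olig1, Olig2, Lhfpl3) differed by a median of 0.154 and 12 other genes by 0.874, a gap of 0.720 (exact permutation of genes, p = 0.0410), which was 0.841 (0.0373) with Sox10 and Nkx2-2 counted as precursor genes and 0.776 (0.0374) without Olig1 and Olig2, but the split was made after the values were seen and the ranges overlapped (-0.187 to 0.190 and 0.0602 to 1.43). A different share of astrocyte lineage cells may have contributed and stays open, since 0 of 15 astrocyte genes were lower in culture 1 than in culture 2 (median difference 0.834), which a change of level within those cells would give as well.

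Immediate early genes were low in culture 1 and high in culture 3. A different share of neurons alone is argued against for the gap between cultures 2 and 3, by the opposite direction of 2 lists. There 11 of 14 immediate early genes were higher in culture 3, by a median of 0.223 (exact sign-flip permutation, p = 0.00781). In contrast, 13 of 19 neuronal genes were lower (median -0.0759), a gap of 0.299 (permutation of 33 genes, p = 0.00048). Both directions had been seen before the tests were chosen, so the p values add no support of their own. A different share of other cells was not tested for this gap. A different share of neurons may account for the low level in culture 1 and stays open. Immediate early genes lay further below the mean of the other cultures than neuronal genes did, by -0.247 (permutation of 33 genes, p = 0.00556), but not detectably further than the 6 GABA genes (-0.102, exact permutation, p = 0.882). Differences in intensity distribution left in the deposited values do not account for the pattern either. The median of culture 3 minus culture 1 was 0.751 after quantile normalization and 0.723 as deposited, with the same limit on a second normalization. How the cultures were handled before RNA was taken is not given in the sources used here and stays open as an untested explanation.

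Cell cycle genes were above background after AraC. Signal without transcript at the rate seen in negative control genes is argued against. With a margin of 1, 19 of 20 cell cycle genes were above background against 1 of 43 negative control genes (Fisher's exact test, p = 6.38e-14). Cross-hybridization particular to single probe sets was not tested, since the probe sets of other genes do not bear on it. Whether the transcripts came from cells that had escaped the drug, or from cells that had begun to divide after it was washed out, was not tested.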
